A study of Arabidopsis arenosa x Arabidopsis thaliana and Arabidopsis thaliana and Arabidopsis arenosa with 5 samples.

How the data were processed

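Rosette leaves of tetraploid Arabidopsis, collected before bolting, gave mRNA libraries of 5 groups: autotetraploid A. thaliana (Landsberg erecta), autotetraploid A. arenosa (Care-1), a resynthesized F1 allotetraploid, an F8 allotetraploid and A. suecica. By the labels, plants grew at 22 °C by day and 20 °C by night with 16 h of light and 8 h of dark, and reads were 60 to 83 bp long. There was 1 table of values per group. Per the file headers and the submitters' description, the deposited values are RPKM of transcripts in the parents and RPKM of each allele in the allotetraploids, computed by the authors before deposit. Per the submitters' processing notes, reads were placed on TAIR 9. The aligner, and how the reads of a gene were divided between alleles, are not given in the sources used here. Allele columns of a transcript add up to a total on the scale of the parents. Depth per library is unknown, because whole reads could not be recovered from most of the RPKM values. The precision that depth gives to a single gene is thus unknown as well.

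The tables list transcripts. The parents' tables hold 38431 transcripts of 32313 genes, and the tables of the F1, F8 and A. suecica 14713, 14334 and 14233 transcripts, of which 13848 (10716 genes) stand in all tables. Each gene was represented by 1 transcript, taken from those listed in all tables where there were any, and among these the transcript with the highest mean over the libraries. The 6 transcripts of ribosomal RNA genes were left out of the comparisons. The F1 table holds only transcripts with both alleles above 0 in each replicate, and those of F8 and A. suecica only totals above 2 RPKM. Gene names and positions are from TAIR10.1, in which 31786 of the gene identifiers were found and 527 were not.

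Before the files were opened, the design assumed 1 library per group and sizes without tests. The tables then turned out to hold 3 replicate columns for each parent and for the F1, and 1 library each for F8 and A. suecica. The size calls stayed the main results as planned, on means of the log2 values of the replicate columns, and a test over the columns was added after seeing the data. Gene lists, filter, pseudocount, size of a call, named-gene rule, window length and the alternatives set in advance were chosen before the data were examined.

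Values were compared as log2(RPKM + 1). Because of the added 1, differences of genes with low values are understated. The parental difference is A. arenosa minus A. thaliana, the allele ratio is the A. arenosa over the A. thaliana allele, the trans term is the parental difference minus the F1 allele ratio, and the mid-parent value is the log2 of the mean of the parents, each parent entering with its mean over replicates on the log2 scale. A gene was compared where the larger parent, or the sum of the alleles, reached 5 RPKM, and was called at 2-fold or more. Tests used limma 3.58.1 in R 4.3.3 with moderated variances that follow the level of the gene (trend), and Benjamini-Hochberg adjusted p below 0.05; F1 alleles were tested on the ratio within each replicate. The trans term was tested in 1 limma model of parents and F1 alleles with a separate spread for each kind, and departures from the mid-parent value with limma's moderated spread carried through the log2 of the mean (delta method). Counts adjusted over a list alone use the same p-values with the adjustment over that list's members. Other work used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

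The lists fixed in advance covered the circadian clock, flowering time, chlorophyll synthesis, starch metabolism, photosynthesis, heat shock and chaperones, cold and abscisic acid response, ethylene, salicylic acid and immune response, jasmonate and wounding, glucosinolate, anthocyanin and trichome, chromatin with DNA methylation and small RNA, cytosolic ribosomal proteins, leaf senescence (for plant age), flower and root (for other tissue), reference genes, and the plastid and mitochondrial genomes. The median of each list was placed among 10000 random lists of the same size, matched on mean RPKM in 10 bins. Levels still vary within a bin, so the match is coarse for lists of very high level. Named genes are the 12 largest differences in each direction for the parents and for the F1 alleles, and the 6 largest in each direction for the other measures, with the higher value at least 20 RPKM and the lower at least 1 RPKM, and the 2 highest and 2 lowest members of each list (exceptions: none). List members named beyond these were chosen after their values were seen. Allele ratios were also taken as medians in windows of 50 consecutive genes. Overlaps of calls between allotetraploids were set against 100 simulations of unchanged groups compared with the same parents, simulated with the spread between F8 and A. suecica.

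The tests were tried on simulated data in which 200 genes had been changed at random. Of genes changed 4-fold, 63% were recovered between the parents, 100% between F1 alleles, 76% for the trans term and 97% against the mid-parent value, and of those changed 2-fold 5%, 83%, 9% and 45%. Unchanged genes called were 2, 12, 5 and 9. Noise was drawn separately for each gene, and many more genes differed between the real parents than were changed here. These rates thus need not hold for the real libraries. Alternatives set in advance were a pseudocount of 0.1 RPKM, a filter of 1 RPKM or none, centring on the median, a 4-fold call, another mid-parent mean, allele ratios from the later allotetraploids and windows of 25 genes. Alternatives added after seeing the data were leaving out each replicate column, genes with 1 listed transcript, a replicate block, and a spread modelled on the allele ratio.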

Results

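Messenger RNA of rosette leaves, taken before bolting, was sequenced in 5 groups of tetraploid Arabidopsis. The groups were an autotetraploid A. thaliana (Landsberg erecta), an autotetraploid A. arenosa (Care-1), an F1 allotetraploid resynthesized from these species, an allotetraploid line of generation F8, and A. suecica, the natural allotetraploid of the same ancestry. The series addresses how regulatory differences that travel with an allele (cis) and differences that act on both alleles (trans) contribute to expression in the allotetraploids. The tables held 3 replicate columns for each parent and for the F1, and 1 library each for F8 and A. suecica. In the allotetraploids each gene had a value for its A. thaliana allele and a value for its A. arenosa allele. Depth per library is unknown, because the values are RPKM (reads per kilobase of transcript, scaled to the mapped reads of the library). The parents' tables listed 32313 genes, and those of the allotetraploids held 11017 genes (F1), 10890 (F8) and 10847 (A. suecica), so genes absent from the shorter tables were compared between the parents only. F8 and A. suecica have no replicate check, and their differences are given as sizes without a test. The labels do not say whether replicate columns came from separate plants, so the p-values below measure the spread between these columns, whatever its source. By the labels the A. thaliana plants were 3 to 4 weeks old and all others 6 to 7 weeks, so age and genotype differ together in every comparison with A. thaliana.

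The replicate libraries differed in their clock genes, and the time of day at which each was collected is not given in the sources used here. CCA1, the morning-phased transcription factor of the circadian oscillator, had 0.258, 7.23 and 24.5 RPKM in A. thaliana replicates 1, 2 and 3, whereas the evening-phased gene TOC1 had 46.9, 13.9 and 7.12 RPKM. In the F1, CCA1 had 0.349, 3.18 and 6.55 RPKM in replicates 1, 2 and 3, and A. suecica had the values 23.7 RPKM for CCA1 and 9.94 RPKM for TOC1. The median log2 level of the 43 photosynthesis genes was 9.19, 10.75 and 11.94 in the A. thaliana replicates. It was 11.33, 11.51 and 11.36 in the A. arenosa replicates, and 9.03, 10.51 and 11.33 in the F1 replicates. For A. thaliana and the F1, these values argue against columns that only repeat 1 RNA sample, but they do not show separate plants. Across genes, A. thaliana replicate 1 had a Spearman correlation of 0.94 with replicate 2, 0.78 with replicate 3 and 0.89 with F1 replicate 1. The correlations among the A. arenosa replicates were 0.93, 0.89 and 0.95, and those among the F1 replicates 0.91, 0.90 and 0.95. Genes are not independent replicates, so these values describe the libraries. In A. arenosa replicate 1, transcripts of ribosomal RNA genes made up 59.6% of the summed RPKM, against 0.232% to 2.56% in the other parental replicates. The median absolute log2 difference between the 2 isoforms of a gene was 0.135, 0.136 and 0.137 in replicate 3 of A. thaliana, A. arenosa and the F1, and 0.136 in F8. Replicates 1 and 2 of these groups had 0.092 to 0.105, and A. suecica 0.205. For low values in the parents, the product of RPKM and transcript length was also checked. It fell on whole multiples of the commonest product in 23.7% and 27.2% of cases in replicate 3 of A. thaliana and A. arenosa. In their replicates 1 and 2 this held for 3.59% to 7.68%, and the allotetraploids were not checked. A processing batch shared by the replicate 3 columns and F8 is therefore possible, and the sources used here name no batches.

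**Figure D1:**
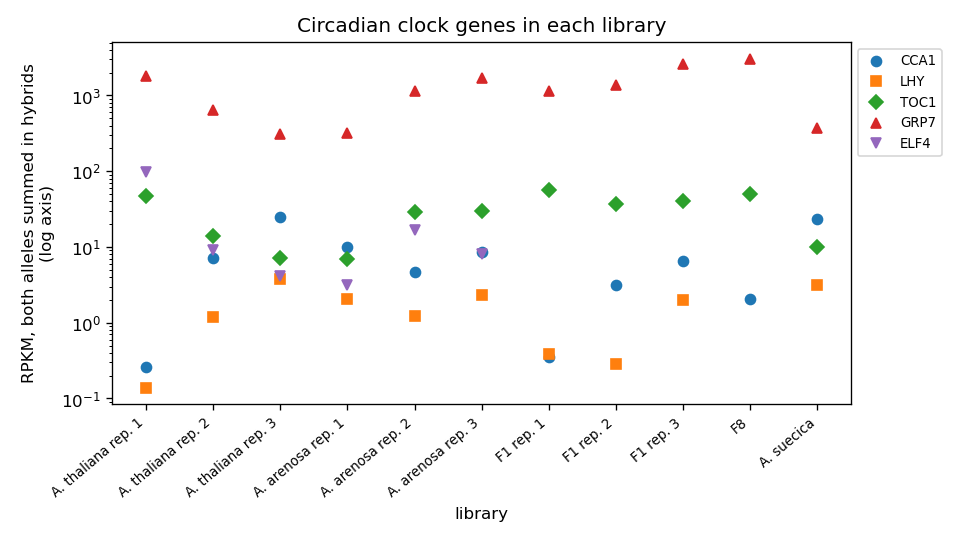
RPKM (log axis) of 5 circadian clock genes in each library, with both alleles summed in the allotetraploids; each point is 1 library. CCA1 ranged from 0.258 to 24.5 RPKM among the A. thaliana replicates, and TOC1 from 7.12 to 46.9 RPKM.

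The comparison of the parents measured how far expression differed between the species. VSP1, PDF1.2c and AT1G72290 were far higher in A. arenosa than in A. thaliana. VSP1, a vegetative storage protein gene on chromosome 5 (8507590 to 8509201, TAIR10.1), had 914 ± 426 RPKM (SD, n = 3) in A. arenosa and 3.16 ± 1.64 RPKM in A. thaliana, a log2 difference of 7.74 (SE 0.44, limma, Benjamini-Hochberg adjusted p = 0.00014). The defensin gene PDF1.2c had 1247 ± 48.3 against 3.11 ± 2.29 RPKM (log2 difference 8.46, adjusted p = 0.00017), and AT1G72290, which encodes a Kunitz-type protease inhibitor, had 2084 ± 919 against 1.82 ± 2.23 RPKM (log2 difference 9.74, adjusted p = 0.00025). FLC, the floral repressor, had 34.2 ± 12.1 RPKM in A. arenosa and 0.529 ± 0.109 RPKM in A. thaliana (log2 difference 4.46, adjusted p = 0.00025). Higher in A. thaliana were ESP, the epithiospecifier gene of glucosinolate breakdown (999 ± 1211 against 8.25 ± 0.987 RPKM, log2 difference -5.85, SE 0.96, adjusted p = 0.0077), the calmodulin-like gene AT2G41090 (601 ± 180 against 4.32 ± 2.59 RPKM) and the ribosomal protein gene RPS6A (91.8 ± 48.5 against 2.27 ± 0.510 RPKM).

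Among the other genes with the widest differences toward A. arenosa were PRB1, a basic relative of PR1 (log2 difference 8.68), the defensin gene LCR67 (8.42), AT1G33840 (7.96), VSP2 (201 ± 157 against 1.03 ± 0.229 RPKM, 6.36), PSBP-2, related to a subunit of photosystem II (6.02), and the jacalin-related gene JAL23 (5.92). Toward A. thaliana they included AT1G67105 (log2 difference -7.07), TIR, a gene of a Toll/interleukin-1 receptor domain (-6.32), the immune-responsive gene LURP1 (-5.21) and ORA47, which encodes a transcription factor of the ERF family (-4.34). All of these passed the test. PDF1.2A and PDF1.2c, VSP1 and VSP2, CBF1 to CBF3, CYP79F1 and CYP79F2, and RPS6A and RPS6B are closely related in sequence. Each member's value is therefore uncertain where reads could be shared, also where 2 members went opposite ways. Reads were placed on TAIR 9, an A. thaliana reference, and its effect on the A. arenosa values was not tested. Below, list members named beyond the 2 highest and 2 lowest of their list were chosen after their values were seen.

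The fixed gene lists differed between the parents in separate ways. Of 12 jasmonate and wounding genes compared, 3 were higher in A. arenosa (VSP1, VSP2 and PDF1.2A at 536 ± 20.0 against 5.55 ± 4.67 RPKM) and none was lower, and the count was 3 when adjusted over the list alone. The biosynthesis gene AOC1 had a log2 difference of 1.61 ± 0.64 (SE) and did not pass. Of 23 glucosinolate genes, 4 were higher in A. arenosa and 4 in A. thaliana, or 8 adjusted over the list alone. The myrosinase gene TGG2 (155 ± 114 against 0.205 ± 0.115 RPKM, log2 difference 6.62) and ESM1 (3.47) were higher in A. arenosa, and the side-chain genes AOP3 (79.5 ± 31.8 in A. thaliana against 0.242 ± 0.0828 RPKM, log2 difference -5.93) and FMO-GSOX1 (-3.76) were higher in A. thaliana. The neighbouring genes CYP79F1 and CYP79F2, whose enzymes begin aliphatic glucosinolate synthesis, went opposite ways, CYP79F1 with a log2 difference of -2.83 (adjusted p = 0.0077) and CYP79F2 with 45.8 ± 5.91 RPKM in A. arenosa against 9.35 ± 2.45 RPKM in A. thaliana (adjusted p = 0.0018). Of 18 cold and abscisic acid genes, the regulators CBF1 (-2.67), CBF2 (-2.94) and CBF3 (-3.10) were lower in A. arenosa, while RD29B (2.93), KIN1 (3.39) and RD20 (2.99), which respond to abscisic acid or cold, were higher; adjusted over the list alone, 7 passed, with ZAT10 (-1.66) added. Of 12 flowering-time genes, FLC and AGL24 (2.34) were higher and MAF2 (-2.18) lower in A. arenosa, 3 also when adjusted over the list alone.

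**Figure D2:**
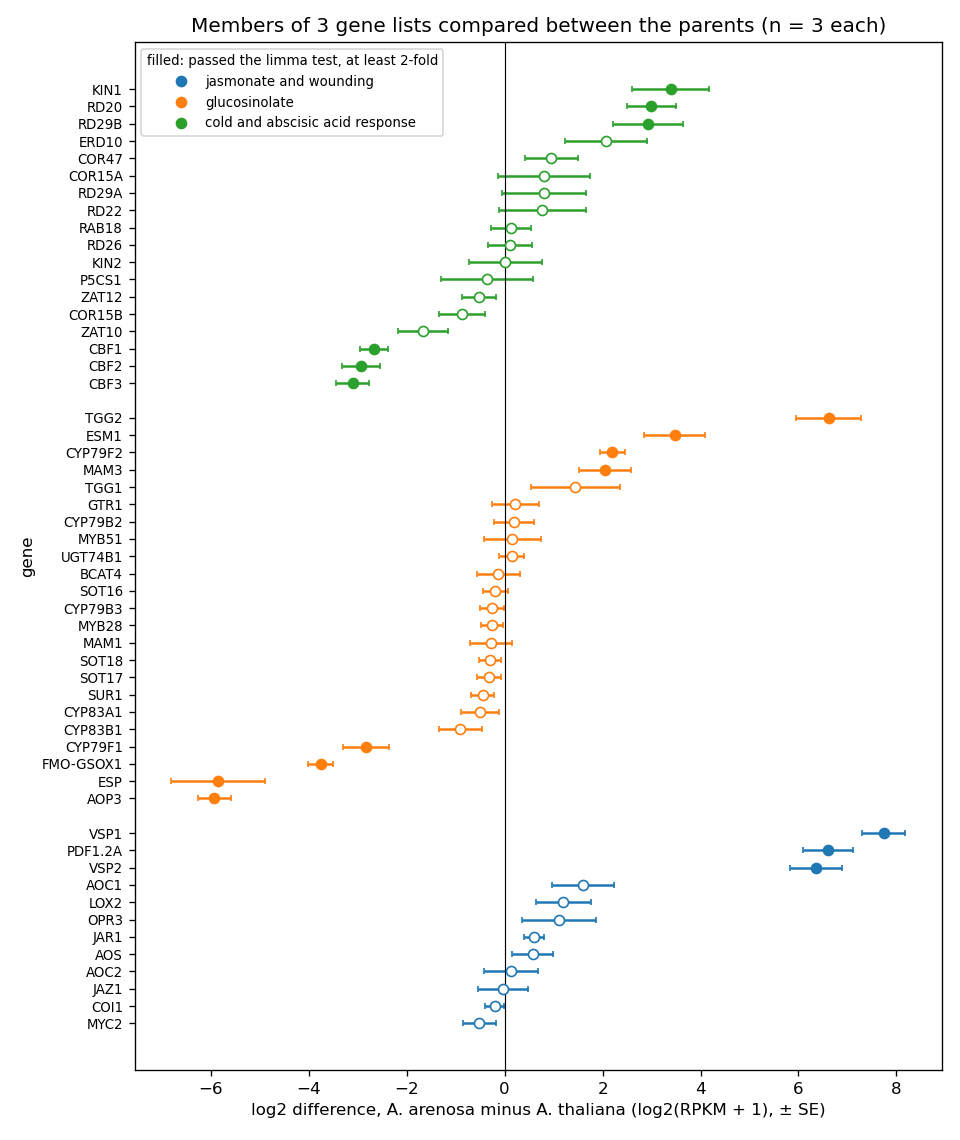
Log2 difference between A. arenosa and A. thaliana (log2(RPKM + 1), points with SE, n = 3 libraries per parent) for each compared member of 3 gene lists; filled points passed the limma test at 2-fold or more. VSP1 (7.74) and TGG2 (6.62) lie far to the A. arenosa side, and AOP3 (-5.93) and ESP (-5.85) far to the A. thaliana side.

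In the ethylene list, 2 of 14 members were higher in A. arenosa, among them ACO4 (2.44), and none was lower; adjusted over the list alone, 4 passed, with ERF2 (-2.03) and ERF5 (-1.03) lower. Of 17 genes for chromatin, DNA methylation and small RNA, AGO1 (34.5 ± 9.68 against 11.3 ± 1.75 RPKM), AGO2 (log2 difference 1.68) and the demethylase gene ROS1 (1.22) were higher in A. arenosa, 3 also adjusted over the list alone. Of 23 ribosomal protein genes, RPS6B (1.76) and RPL10B (1.71) were higher and RPS6A (-4.72) lower, 3 adjusted over the list alone. Of 8 anthocyanin and trichome genes, FLS1 (2.88) and CPC (1.64) were higher, and 3 passed adjusted over the list alone, with F3H (2.18) added. In the starch list LDA (-1.96) alone of 22 passed, in the heat shock list HSP70 (1.60) alone of 6, and in the salicylic acid list ACD6 (-2.18) alone of 21; adjusted over the list alone the counts were 1, 1 and 0. The reference genes had UBC9 (1.13) of 13, and 0 adjusted over the list alone. None of 19 clock, 12 chlorophyll synthesis, 43 photosynthesis, 11 senescence or 2 root genes passed, nor did any when adjusted over those lists alone; the median log2 differences were 0.26, 0.71, 0.65, 0.15 and 0.15. Of the flower markers only SEP2 reached the filter (13.7 ± 4.85 against 0.106 ± 0.0515 RPKM, log2 difference 3.67, 1 adjusted over the list alone). The lists of plastid and mitochondrial genes had 0 members in these tables.

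Across 12739 genes compared between the parents, 2207 were at least 2-fold higher in A. arenosa and 803 at least 2-fold higher in A. thaliana. Under limma at an adjusted p below 0.05, 1359 and 536 of the 2-fold differences passed. The median gene was higher in A. arenosa by 0.31 on the log2 scale, and centring on that median gave 1418 and 1244 genes by size and 866 and 816 by test. The tested counts were 2242 and 807 without A. thaliana replicate 3, 775 and 297 without A. thaliana replicate 2, and 721 and 324 without A. arenosa replicate 2.

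Within the F1, both alleles of a gene share 1 nucleus, so their ratio measures cis differences if reads were divided correctly between the alleles. How reads were divided is not given in the sources used here, so this could not be checked. Photosynthesis genes had more transcript from the A. arenosa allele. PSBR, which encodes a photosystem II subunit, had 3014 ± 2544 RPKM (SD, n = 3) from the A. arenosa allele and 385 ± 271 RPKM from the A. thaliana allele, a log2 ratio of 2.83 (SE 0.14, limma, adjusted p = 0.00086), and the light-harvesting gene LHCB2.1 had a log2 ratio of 2.57 (SE 0.15, adjusted p = 0.0012). Of the 43 photosynthesis genes 17 had an A. arenosa allele higher by 2-fold or more and none an A. thaliana allele, 17 also when adjusted over the list alone; at any size 37 and 2 genes passed, the latter being PETE2 (-0.55) and FBA1 (-0.86). The median log2 ratio of the list, 0.94, lay at percentile 99.98 among 10000 random lists matched on level. Genes of high level outside the list, which could include other photosynthesis genes, leaned the same way. The 469 with the highest levels had median log2 ratios of 0.66, 0.58 and 0.54 in replicates 1, 2 and 3. Across genes the ratio rose with level in the F1 (Spearman 0.25, 0.24 and 0.19) but not in F8 or A. suecica (-0.03 and -0.02). Toward A. thaliana, the glucosinolate gene ESP had 579 ± 594 RPKM from the A. thaliana allele and 0.310 ± 0.208 RPKM from the A. arenosa allele (log2 ratio -8.23, adjusted p = 0.0019), and PR2, a glucanase gene of the salicylic acid response, had 228 ± 170 and 0.309 ± 0.246 RPKM (log2 ratio -7.02, adjusted p = 0.0019).

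Among genes with both alleles at 1 RPKM or more, the widest ratios toward A. arenosa included the chitinase-family gene AT2G43590 (log2 ratio 6.47, adjusted p = 0.0034), AT3G54400 (5.71), AT3G45030 (4.80), the tubulin gene TUB5 (A. arenosa allele 123 ± 47.3 RPKM, A. thaliana allele 3.12 ± 4.95 RPKM, log2 ratio 5.56) and the light-harvesting gene LHB1B2 (5827 ± 4675 and 273 ± 180 RPKM, log2 ratio 4.36); the ratio of the photosystem I gene PSAH-1, 4.47, did not pass (adjusted p = 0.083). Toward A. thaliana, under the same limit, they included TCH3, a calmodulin-like gene of the touch response (A. thaliana allele 205 ± 51.0 RPKM, A. arenosa allele 1.78 ± 2.54 RPKM, log2 ratio -6.55, adjusted p = 0.0012), the ubiquitin genes UBQ3 (-5.43) and UBQ1 (-5.38, adjusted p = 0.017), the invertase inhibitor gene C/VIF2 (-4.70), AT3G48640 (-4.00) and GGR (-3.70). LHCB, RBCS, ubiquitin and tubulin genes have close relatives, with which reads could be shared.

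In the F1 most of the other lists held more A. arenosa than A. thaliana calls, as did all 10223 genes together (866 and 452 tested calls). In the cold and abscisic acid list 4 of 13 genes had a higher A. arenosa allele, among them RD20 (log2 ratio 2.55) and RD26 (1.73), and none a higher A. thaliana allele, 4 adjusted over the list alone. In the glucosinolate list 5 of 20 were higher from A. arenosa, including ESM1 (2.46) and MAM3 (2.36), and 2 from A. thaliana (ESP and CYP79F1, -2.04), 7 adjusted over the list alone. The jasmonate list had 3 of 9 toward A. arenosa (AOC1 2.72, AOC2 1.65, LOX2 1.23; 3 adjusted over the list alone), and the ribosomal list 5 of 22 (RPL10B 2.23, RPL10C 2.06; 5 adjusted over the list alone). The reference genes had 4 of 13 toward A. arenosa (ACT7 1.62, GAPC2 1.34; 4 adjusted over the list alone). The salicylic acid list was mixed, with WRKY18 (1.27) and EDS1 (1.25) toward A. arenosa and PR2, ACD6 (-1.92) and PR5 (-1.85) toward A. thaliana, 5 of 16 and 5 adjusted over the list alone. Starch (GBSS1 1.62, APS1 1.23, APL1 1.05), chromatin (AGO2 1.51, RDR6 1.23 and AGO1), ethylene (ACO4 1.59), chlorophyll (PORC 1.34, CRD1 1.11), heat shock (HSC70-1 1.39, HSP90.2 1.11) and clock (GRP7 1.54) calls were all toward A. arenosa, with 3, 3, 2, 2, 2 and 1 genes, the same counts as adjusted over the list alone. FLM (-1.64) was the flowering-time gene that passed, CHS (-1.05) and F3H (1.22) the anthocyanin genes, with 1 and 2 adjusted over the list alone. None of 9 senescence or 2 root genes passed at 2-fold, nor when adjusted over the list alone. These counts do not by themselves set a list apart from genes of its level. Against matched random lists, the median ratio of the starch list lay low (-0.03, percentile 3.41). Those of the jasmonate, glucosinolate and ribosomal lists lay at percentiles 53.2, 70.4 and 76.9, and those of the cold and abscisic acid and reference lists at 95.9 and 97.8.

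Over 10223 genes, 906 had an A. arenosa allele and 482 an A. thaliana allele at least 2-fold higher, and 866 and 452 of these passed the limma test. The median log2 ratio over all genes was 0.05. Of 621 tested genes higher in the A. arenosa parent with F1 alleles compared, 589 had an F1 ratio of the same sign and 277 a tested 2-fold call of the same direction, with 0 in the opposite direction; their median log2 difference was 1.45 between the parents and 0.92 between the F1 alleles. Of 163 higher in the A. thaliana parent, 154 had the same sign and 101 the same call, with 0 opposite. These genes were chosen for their parental difference, so a smaller F1 median shows no trans effect by itself. They are a part of the 1359 and 536 tested parental differences. Genes with an allele at 0 in any F1 replicate were not listed and are not covered. Across 9857 genes, which are not independent replicates, the parental difference and the F1 allele ratio had a Spearman correlation of 0.61.

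The trans term was the parental log2 difference minus the F1 allele ratio. An error in dividing reads between the alleles would enter the allele ratio and, with opposite sign, the trans term. TCH3 had a log2 trans term of 4.92 (SE 0.60, limma, adjusted p = 0.0087), from a parental difference of -1.64 and an F1 allele ratio of -6.55. C/VIF2 had 4.13 (SE 0.61, adjusted p = 0.034) and AT1G27030 had 3.20 (SE 0.46, adjusted p = 0.030). AT1G27030 had 97.7 ± 16.2 RPKM (SD, n = 3) in A. arenosa against 4.33 ± 3.47 RPKM in A. thaliana, and 38.2 ± 21.1 against 15.9 ± 8.26 RPKM between its F1 alleles. Other wide terms did not pass: UBQ1 5.91 (adjusted p = 0.15), TIM9 of the mitochondrial import machinery 3.76 (adjusted p = 0.056), and in the opposite direction TUB5 -4.89 (adjusted p = 0.096) and LHB1B2 -3.15 (adjusted p = 0.14). No member of any list passed over all genes. Adjusted over the list alone, PR2 (4.55) and WRKY33 (-1.48) passed in the salicylic acid list, HSP90.2 (-1.27) in the heat shock list and CHI (AT3G55120, -1.23) in the anthocyanin list, and 0 in the others. The photosynthesis, glucosinolate and cold and abscisic acid lists had median trans terms of -0.20, -0.36 and -0.36, at percentiles 2.69, 0.11 and 1.12 of matched random lists. The heat shock (-0.60, percentile 1.18), anthocyanin (-0.37, percentile 1.73) and senescence lists (-0.40, percentile 0.775) lay as low. Since the senescence list stands for plant age, these medians are not separated from age. The anthocyanin median was 0.11 among genes with 1 listed transcript.

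Of 9857 genes, 936 had a cis difference of at least 2-fold without such a trans term and 621 a trans term without such a cis difference. In 392 both were present with opposite signs, in 37 with the same sign, and 7871 had neither. By size, 717 trans terms were above and 333 below 0 by 2-fold; centred on the median term of 0.23 they were 394 and 540, and at a 4-fold call 48 and 51, so the larger side turned in both. Under limma 5 above and 11 below passed, with 1520 genes at an unadjusted p under 0.05 in all. The terms above 0 that passed numbered 402 without A. thaliana replicate 3, 22 without F1 replicate 3, 12 without A. arenosa replicate 1, 2 without A. thaliana replicate 1, F1 replicate 1 or F1 replicate 2, and 0 without A. thaliana replicate 2 or A. arenosa replicate 2 or 3, so this count rests on single libraries. Those below 0 numbered 94 without A. thaliana replicate 3, and 7, 6 and 5 without A. thaliana replicate 2, A. arenosa replicate 2 and A. arenosa replicate 3, and without A. thaliana replicate 3 the sizes were 1243 above 0 and 1137 with a trans term only. Across genes, the allele ratio and the trans term had a Spearman correlation of -0.46 with the F1 in both terms, -0.27 with the trans term from F8 and -0.06 from A. suecica.

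The total of both F1 alleles was compared with the mid-parent value, the mean of the parents. AT1G19380 was higher in the F1 (152 ± 42.5 RPKM, against 16.2 ± 6.33 in A. thaliana and 11.7 ± 6.71 in A. arenosa, log2 departure 3.40, SE 0.35, limma, adjusted p = 0.029), as was WRR4, a resistance gene against white rust (79.1 ± 42.7 RPKM against 13.7 ± 3.87 and 6.49 ± 1.73, log2 departure 2.74, SE 0.32, adjusted p = 0.029). The expansin-like gene EXLA1 had a departure of 2.81 (adjusted p = 0.17), and among the lowest were ANK (-4.19, adjusted p = 0.093) and the iron superoxide dismutase gene FSD1 (-2.05, adjusted p = 0.083); none of these passed. No list member passed over all genes. Adjusted over the list alone, WRKY33 (1.59) and WRKY40 (1.67) passed in the salicylic acid list, JAZ1 (1.88), a repressor of jasmonate signalling, in the jasmonate list, ERF4 (1.32) in the ethylene list, and 0 in the others. The cold and abscisic acid list had a median departure of 0.82 (percentile 99.98 of matched random lists), with COR15B at 1.71 and RD29A at 1.53; its level was 5.57, 7.41 and 7.23 in F1 replicates 1, 2 and 3, against 4.15 to 5.78 in A. arenosa, so replicate 1 lay within the range of that parent. The senescence list, a check of plant age, also lay above (0.58, percentile 99.6, 3 of 9 genes 2-fold above and 0 below), so age is not separated from these departures. The photosynthesis list had a median of -0.70 (percentile 0), with LHCB2.1 at -1.45; its log2 level in the F1 lay below both parents of the same number in each replicate (9.03 against 9.19 in A. thaliana and 11.33 in A. arenosa, 10.51 against 10.75 and 11.51, and 11.33 against 11.94 and 11.36), in replicates 1 and 3 by little against the nearer parent, and the F1 levels spread wider than the departure.

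Of 10055 genes, 401 lay at least 2-fold above and 127 at least 2-fold below the mid-parent value; centred on the median departure of 0.16 they were 267 and 195. Under limma 9 above and 0 below passed, with 1662 genes at an unadjusted p under 0.05. The 9 became 27 with the geometric mean of the parents, 14 with a replicate block, 4 with a pseudocount of 0.1 RPKM, 3 among genes with 1 listed transcript and 1 after centring. The tested count above was 20 without A. thaliana replicate 3, 14 without A. arenosa replicate 1, 1 without A. arenosa replicate 2 and 0 without A. thaliana replicate 2, A. arenosa replicate 3, or F1 replicate 2 or 3, and the count below was 3 without F1 replicate 1. By size, 246 lay above without A. arenosa replicate 1, and 201 and 223 below without A. thaliana replicate 1 and F1 replicate 3. Of 1494 genes at least 2-fold different between the parents, 61.6% had an F1 total closer to A. arenosa. The 95% exact binomial interval, which covers genes as counted only, was 59.1 to 64.1%. The share was 48.2% after centring and 72.2% without A. thaliana replicate 3. Closeness was taken on the log2 scale, where a total equal to the mean of the parents lies closer to the higher parent. Most tested divergent genes with F1 alleles were higher in A. arenosa (621 against 163), so additive totals alone would put most of them closer to A. arenosa. The share thus shows no lean of the F1 by itself. It was not set against the share that additive totals would give, so additivity is not shown either.

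In F8, the genes of salicylic acid defence had low totals. PR1, the marker gene of that response, had 40.3 RPKM in F8 against 404 ± 263 RPKM (SD, n = 3) in A. thaliana and 823 ± 560 RPKM in A. arenosa, a log2 departure of -3.64 from the mid-parent value. PR2 (-3.33), the transcription factor gene WRKY70 (-3.32) and PR5 (-2.82) were also lower, and 9 of the 16 genes of the list lay 2-fold below and 0 above (median -1.09, percentile 0 among matched random lists). The median log2 level of the list was 3.96 in F8, but A. thaliana replicate 3 (4.03, against 5.17 and 5.07 in replicates 1 and 2) and F1 replicate 2 (4.24) lay almost as low. The cold and abscisic acid list lay above (median 1.18, percentile 100, 7 of 13 genes 2-fold above and 1 below), with RD29A at 2.53 and COR15B at 2.43, as did the starch list (median 0.85, percentile 100, 7 of 21 above and 0 below, PHS2 1.65 and PWD 1.37), the ribosomal list (0.82, percentile 99.9, 5 of 22 above and 0 below) and the clock list (0.74, percentile 99.9, 6 of 14 above and 1 below, GRP7 1.96 and CCA1 -1.29). The level of the starch list was 5.81 in F8, beside 5.75 in A. thaliana replicate 3, against 4.81 and 4.43 in replicates 1 and 2. In the glucosinolate list 6 of 20 genes lay below and 1 above (MYB51 -1.48, CYP79B2 -1.35, ESP 2.60). The widest departures of single genes were AT1G51402 (464 RPKM, log2 departure 4.89) and AT3G15450 (2.93) above, and the chitinase-family gene AT3G47540 (4.73 RPKM, -4.71) and the glucanase gene BG3 (-4.17) below.

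The widest departures in A. suecica belonged to genes of several functions. The lipid transfer gene LTP4 had 1719 RPKM against 48.5 ± 81.1 RPKM (SD, n = 3) in A. thaliana and 4.07 ± 2.66 RPKM in A. arenosa (log2 departure 8.02), the proline synthesis gene P5CS1 319 RPKM (4.38), the wax synthesis gene CER1 152 and 104 RPKM from its A. thaliana and A. arenosa alleles (4.33), the drought-response gene RD22 2995 RPKM (4.22) and the glucosinolate gene ESM1 1978 RPKM (4.39). CSD2, a copper and zinc superoxide dismutase gene of the chloroplast, had 9.17 RPKM against 312 ± 370 and 609 ± 305 RPKM in the parents (log2 departure -5.12), and AT2G43590 had -4.89. The starch list lay above the mid-parent value (median 1.05, percentile 99.99, 13 of 21 genes 2-fold above and 0 below, among them SS3 and DPE2, the latter at 2.17), as did the photosynthesis list (0.66, percentile 99.99, 13 of 43 above and 0 below). The ribosomal list lay below (median -0.69, percentile 0, 0 of 22 above and 4 below, RPL10B -2.12), as did the salicylic acid list (-0.67, percentile 0.03, 1 of 15 above and 5 below, WRKY18 -3.70, PR5 -3.48, ACD6 2.52) and the senescence list (-0.83, percentile 0.23, 1 of 6 above and 3 below). The log2 level of the ribosomal list, 5.62, was near those of A. thaliana replicates 1 and 2 (5.81 and 5.72), while A. thaliana replicate 3 had 6.95. The photosynthesis list, at 11.51, lay within the parental libraries (11.33 to 11.51 in A. arenosa, 11.94 in A. thaliana replicate 3), and its departure rests on A. thaliana replicates 1 and 2 (9.19 and 10.75). The cold and abscisic acid list was mixed, with 5 of 13 above and 3 below (percentile 92.0). Because the clock genes differ between libraries and collection times are unknown here, departures of the clock, starch, cold and photosynthesis lists in these single libraries are not separated from time of day.

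By size, 654 of 9994 genes in F8 lay above and 432 below the mid-parent value, or 384 and 607 centred on the median of 0.17. In A. suecica 1423 of 9921 lay above and 522 below, or 583 and 983 centred on the median of 0.35, so the larger side turned in both groups after centring, as it did at a 4-fold call (34 and 70 in F8, 105 and 128 in A. suecica). Of the parent-divergent genes, 70.3% (67.9 to 72.6%) in F8 and 54.6% (52.0 to 57.2%) in A. suecica had totals closer to A. arenosa, against 62.8% and 43.2% after centring and 83.4% and 67.2% without A. thaliana replicate 3. Without A. thaliana replicate 1 they were 63.4% and 48.6%, so the side in A. suecica depends on a single parental library. As in the F1, additive totals lie closer to the higher parent, mostly A. arenosa, so these shares show no lean by themselves. Nor were they set against the shares that additive totals would give. F1 and F8 shared 149 genes above and 58 below, where independent lists share 22.4 and 4.56 and simulated unchanged groups against the same parents 31.1 and 38.2; the covariance of their departures was 0.142 against 0.0349 simulated. F1 and A. suecica shared 28 above (independent 49.6, simulated 29.9) and 17 below (5.65 and 37.6), with a covariance of -0.0350 against 0.0350. F8 and A. suecica shared 133 above (91.3 and 31) and 123 below (21.4 and 37.1), with a covariance of 0.0902 against 0.0352. Part of any excess of shared genes may come from the shared parental libraries, which are too few to split. The simulated groups had the spread between F8 and A. suecica, which may hold real differences, also in the pairs with the F1. Departures varied less across genes in the F1 (SD 0.459) than in A. suecica (0.793). For pairs with the F1 the simulated counts are thus no matched reference.

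Allele ratios in the later allotetraploids were set against the F1. Of 1245 F1 allele calls also compared in F8, 1221 (98.1%) had the same direction and 3 were 2-fold in the opposite one, and of 1209 compared in A. suecica 995 (82.3%) had the same direction and 68 were 2-fold in the opposite one. The photosynthesis genes departed from their F1 ratios. Their median shift was -1.04 in F8 (percentile 0 among matched random lists, 24 of 43 genes 2-fold toward A. thaliana and 0 toward A. arenosa) and -1.20 in A. suecica (percentile 0, 28 toward A. thaliana and 2 toward A. arenosa). The 20 genes outside the list nearest in level to each member had median shifts of -0.92 in F8 and -0.56 in A. suecica. Genes of that level thus moved the same way, but other photosynthesis genes could be among them, and members of high level share neighbours. Below their neighbours lay 33 of 43 members in F8 and 33 in A. suecica. LHCB2.1 had log2 ratios of 2.57 in the F1, 0.79 in F8 and -1.37 in A. suecica, and PSBO2 had 1.77, 1.17 and 0.56. In A. suecica the A. thaliana allele of PSBR was listed at 0 beside 6518 RPKM of the A. arenosa allele. The cold and abscisic acid list shifted toward A. thaliana in A. suecica (median -1.01, percentile 1.47, 6 of 10 genes 2-fold and 0 toward A. arenosa, RD29A -2.13).

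**Figure D3:**
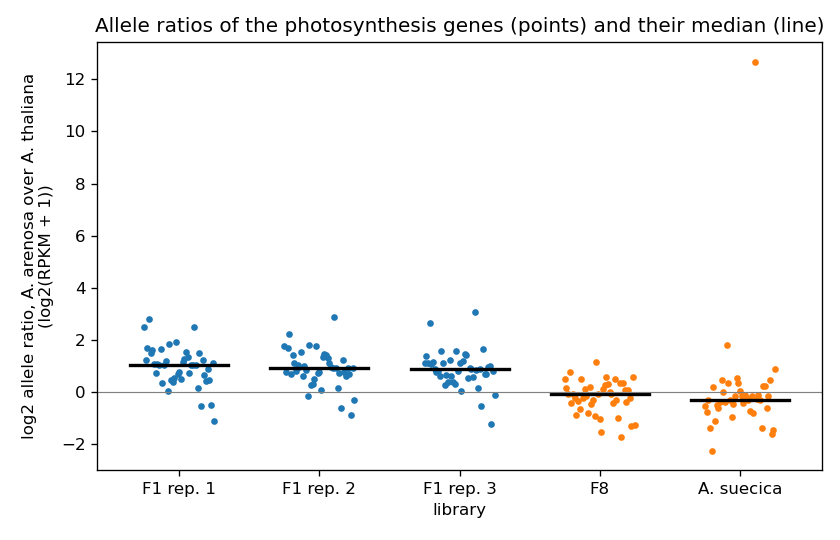
Log2 ratio of the A. arenosa over the A. thaliana allele (log2(RPKM + 1)) for 43 photosynthesis genes in each allotetraploid library; points are genes and lines medians. The medians are 1.04, 0.92 and 0.88 in the F1 replicates, -0.08 in F8 and -0.29 in A. suecica; the highest A. suecica point is PSBR, whose A. thaliana allele is listed at 0.

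Single genes shifted further. In F8, AT1G04800, which encodes a glycine-rich protein, had 1.16 RPKM from the A. arenosa and 92.0 RPKM from the A. thaliana allele, a shift of -6.33 from its F1 log2 ratio, and RbcX1, of Rubisco assembly, had a shift of -3.87, while the ribosomal protein gene AT4G34670 (4.26) and the glucosinolate gene MAM3 (3.64, with 319 RPKM from the A. arenosa and 3.99 RPKM from the A. thaliana allele) shifted toward A. arenosa. In A. suecica MAM3 shifted the opposite way (-4.45), as did AGP16 (-6.08) and the ribosomal protein gene AT1G04480 (-5.64), while the chloroplast RNA-binding gene CSP41A (6.36), MGL (4.73) and SKIP1 (4.08) shifted toward A. arenosa. By size, 339 genes in F8 shifted 2-fold toward A. arenosa and 405 toward A. thaliana of 9569, and in A. suecica 926 and 1151 of 9565. At a 4-fold call the larger side turned in both (85 and 57 in F8, 281 and 267 in A. suecica), and with a pseudocount of 0.1 RPKM 529 genes of F8 shifted toward A. arenosa, so no lean of the shifts is given. Across genes, F1 ratios had a Spearman correlation of 0.75 with F8 and 0.45 with A. suecica. None of 180 windows of 50 consecutive genes departed by 2-fold from its library's median and from the other libraries. Genes at the chromosome ends that filled no such window were left out, on chromosome 3 those past AT3G62750. In windows of 25 genes, a choice also made before the data were examined, 2 of 362 did so, both in A. suecica and both at the distal end of chromosome 3.

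At that end of chromosome 3, A. suecica had no listed transcript from the A. thaliana allele of most genes. Between ARFA1E (AT3G62290) and the carotenoid cleavage gene CCD1 (AT3G63520), positions 23051544 to 23456078 of TAIR10.1, it listed 58 genes, and in 45 of them (77.6%) the A. thaliana allele was listed at 0, against 145 of 10728 genes elsewhere (1.35%). ARFA1E had 671 RPKM, CCD1 244 RPKM and EMB3126 142 RPKM, all from the A. arenosa allele. The other members still had some A. thaliana transcript, among them CP12-2, a regulator of the Calvin cycle (125 RPKM), and CSP41A (24.8 RPKM). F8 listed 60 genes of the segment, with the A. thaliana allele at 0 in 1, and the median A. thaliana share of the total was 51.6% in the F1, 52.3% in F8 and 0% in A. suecica. The segment's bounds and the genes named in it were chosen after the values were seen, and transcript levels cannot give the copy number of its genes.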

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

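The tests of these patterns were chosen only after the result was seen, except those on shared reads and on the level of the genes, which were written before. Allele ratios of F8 or A. suecica opposite to that of each F1 replicate were flagged as differences between groups, which were not tested. In F8 the ratio of AT1G04800 differed from the F1 by -6.33, AT3G16670 by -4.89 and AT4G23670 by -3.97 on the log2 scale, all toward A. thaliana. In A. suecica CSP41A differed by 6.36 and HIR2 by 4.82 toward A. arenosa, and AGP16 by -6.08, AT1G04480 by -5.64, AT1G75280 by -5.10, AT3G47540 by -4.98, MAM3 by -4.45 and TLL1 by -4.35 toward A. thaliana. The F1 ratios behind some of these vary widely between replicates 1, 2 and 3: -6.22, -2.57 and -1.11 for CSP41A, -5.87, -1.43 and -0.23 for HIR2, 0.73, 1.69 and 7.20 for AGP16, and 3.10, 2.05 and 5.82 for AT3G47540. A share of ribosomal RNA of 59.6% in A. arenosa replicate 1, in transcripts that no comparison used, was flagged as a signal outside the main measurement.

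At the distal end of chromosome 3, A. thaliana alleles were listed at 0 in 45 of 58 genes in A. suecica. An allele assignment fault shared by all libraries is excluded, since F8 had 1 such gene in the segment. The total of both alleles, A. suecica minus F8, differed from that elsewhere by only -0.0933, and the A. arenosa allele was higher by 1.01 relative to other genes. Replacement of the A. thaliana copy by a further A. arenosa copy predicts both values. A deletion without replacement in which the remaining A. arenosa copies are raised gives them too. Neither predicts A. thaliana transcript in the segment, yet CP12-2 had 125 RPKM of it. AT3G62400 had 10.7 RPKM from the A. thaliana and 0 from the A. arenosa allele, the only gene of the segment with that allele at 0. The cause of these values was not tested. Replacement and deletion cannot be told apart, because RNA levels cannot give copy number, and both remain hypotheses. An assignment fault in A. suecica alone, with A. thaliana reads counted as A. arenosa, would give the same values and was not tested.

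The photosynthesis genes leaned toward A. arenosa in the F1 but not in F8 or A. suecica. Reads shared between near-identical paralogs are argued against, as members with few shared sequences shifted by -0.99. A processing batch stays open. F1 replicate 3 resembles F8 but not A. suecica in how close the values of isoforms lie, as do replicate 3 of A. thaliana and of A. arenosa. F1 replicate 3 kept a median ratio of 0.88, but this is 1 library. A trend with the level of the gene stays open for F8. Genes nearest in level shifted almost as far, the median difference to them being -0.20, though 33 of 43 members lay below them. Only the list's own members were kept out of these neighbours, so other photosynthesis genes, such as LHB1B2, could be among them. Members of high level also share neighbours, so the 43 comparisons are not separate. A level trend is thus not told apart from a shift of photosynthesis genes. In A. suecica the list lay -0.57 beyond its neighbours in level, so the trend leaves part of that shift open, and no biological explanation was tested.

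Cis and trans differences in opposite directions outnumbered those in the same direction 10.6 to 1. With the cis term from 1 F1 replicate and the trans term from the others the lowest ratio was 2.56. Error of single F1 replicates in both terms thus raises the excess but is not its whole cause. Among genes that share no sequence with another gene the ratio was 7.29, and 2.14 with replicates separated, against 16.7 among genes that share some, so shared reads are argued against as the whole cause and stay open as part of it. An assignment error recurring in every hybrid stays open: the ratio was 1.39 with the allele ratio of A. suecica in the trans term, but differences of A. suecica in its own alleles also lower it, and with F8 it was 3.93. No biological explanation was tested.

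Other splits of the libraries were run for the tested counts. For the parents (1895 genes; highest other split 0) 1 of 10 splits and for the F1 alleles (1318; 0) 1 of 4 splits called as many, and these are too few splits for a share under 0.05. For the trans term 5 of 10 splits called at least the real 16 genes, the highest 256, but these splits exchanged the parents alone and kept the F1 allele ratio in the term. For the mid-parent comparison 6 of 100 called at least the real 9, but they mixed the species, and the highest, 519, set all 3 A. thaliana libraries against mixtures of the others. Differences between the species thus enter these splits, and they say nothing on chance for either count.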

How the results depend on the processing

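No named gene with a call changed direction. The larger side turned for trans terms and for totals of F8 and A. suecica, both after centring and at a 4-fold call, and for shifted allele ratios of F8 and A. suecica at a 4-fold call. After centring, the F1 and A. suecica shares closer to A. arenosa came to lie below those closer to A. thaliana. Medians of some lists also changed sign, such as that of the clock list between the parents (-0.06 after centring) and of the cold and abscisic acid list (-0.52 with 1 listed transcript). The median trans term of the anthocyanin list went from -0.37 to 0.11 with 1 listed transcript. Of the counts and shares of the comparisons, 133 stayed within 1.5 times (or their interval) under other settings and 53 did not, and 136 and 47 when 1 library was left out. Single named genes with a test stayed on their side of the threshold in 3425 of the values without 1 library, with 48 passing newly and 66 no longer; under other settings 2082 values of named genes stayed, 59 without a test moved by more than the spread between replicates, 8 passed newly and 8 no longer. The cause was not tested for any of the changes below, except that a 4-fold call and left-out libraries leave fewer genes or samples by construction. Depth is unknown, so how far it limits genes with low values cannot be given. The limma tests were chosen after seeing the data.

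With a pseudocount of 0.1 RPKM, 529 genes of F8 shifted toward A. arenosa, 19 tested trans terms lay below 0 and 4 tested F1 totals above the mid-parent value. With a filter of 1 RPKM or none, 1284 genes were higher in A. thaliana, and the tested parental counts were 2244 and 909 at 1 RPKM and 2044 and 812 with no filter. Centred on the median, the parents gave 1418 and 1244 (tested 866 and 816), trans terms 394 and 540 (tested above 3), F1 totals 267 and 195 (tested above 1), F8 totals 384 above, and A. suecica totals 583 and 983, and the shares closer to A. arenosa were 48.2% (F1), 62.8% (F8) and 43.2% (A. suecica). The geometric mean of the parents gave 27 tested F1 totals above. With the allele ratio of F8, trans terms were 1383 and 590, with 1005 genes trans only; the relation of cis and trans was -0.27 with F8 and -0.0588 with A. suecica. In windows of 25 genes, 2 departed in A. suecica.

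At a 4-fold call, the parents gave 683 and 314, F1 alleles 154 and 75, trans terms 48 and 51, cis only 174, trans only 45, F1 totals 31 and 4, F8 totals 34 and 70, A. suecica totals 105 and 128, and shifted ratios 85 and 57 in F8 and 281 and 267 in A. suecica.

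Among settings chosen after seeing the data, genes with 1 listed transcript gave 2 tested trans terms above 0 and 3 tested F1 totals above, and a replicate block gave 14 F1 totals above and 0 below (parents 1298 and 503). A spread modelled on the allele ratio gave 874 and 452 F1 alleles. The numbers were not taken as pairs, since same-numbered libraries did not deviate together in all groups: correlations of their deviations were 0.01, -0.12 and 0.14 between A. thaliana and A. arenosa, 0.53, -0.26 and 0.24 between A. thaliana and the F1, and 0.29, 0.31 and 0.29 between A. arenosa and the F1, the only groups in which all 3 deviated together. Each library of these 2 groups deviated most like its own number in the other, which did not hold with A. thaliana.

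Leave-one-out ranges, also chosen after seeing the data, were 590 to 1243 for trans terms above 0, 588 to 1137 for trans only, 246 to 586 and 96 to 223 for F1 totals above and below, and for tests 721 to 2242 and 297 to 807 (parents), 0 to 402 and 5 to 94 (trans terms above and below 0), and 0 to 20 and 0 to 3 (F1 totals). Shares closer to A. arenosa ranged from 54.2 to 72.2% (F1), 63.4 to 83.4% (F8) and 48.6 to 67.2% (A. suecica).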

Other observations

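In F8, 6 neighbouring genes of chromosome 3, from the brassinosteroid synthesis gene DWF4 (AT3G50660) to BEH1 (AT3G50750), positions 18813949 to 18863397 of TAIR10.1, had the A. thaliana allele listed at 0, where shuffled gene orders gave runs of at most 3. A. suecica had both alleles of these genes above 0. The F1 did too, but its table holds only transcripts with both alleles above 0, so it could not show such a run. The run was noticed after the values were seen, and it was not tested further. In A. suecica the longest such run was 10 genes, from AT3G63340 to CCD1, inside the segment described above.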
